A study of Mus musculus with 12 samples.

How the data were processed

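The authors deposited a table of read counts for 49671 genes and 92 ERCC spike-in transcripts in 12 libraries, with a column per library. According to the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to the mm10 mouse genome with STAR 2.5.2b and counted per gene with featureCounts of Subread 1.5.2, and differential expression was run in edgeR. The annotation release and the strand setting of the counting were not given in the sources used here. The library kit named by the submitters is not described as keeping the strand. Where genes overlap on opposite strands, such as Dlx1 and Dlx1as, reads may have been left out or given to the wrong gene, although each gene was counted separately. The authors also deposited result tables whose fold changes are in log2 units and whose test columns hold p-values and false discovery rates (FDR) from edgeR. Of the genes counted, 49326 were found by identifier in GENCODE M21, from which coordinates on GRCm38 were taken, and 174 had no symbol.

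The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter, which left 15758 genes, and library sizes were scaled by TMM factors computed without the spike-ins. All 12 libraries entered a single quasi-likelihood fit by group, and 3 comparisons were tested with Benjamini-Hochberg adjusted p-values under 0.05. Levels are given as CPM (counts scaled to a common library size; group mean and SD over 4 libraries), and fold changes as log2 values with their standard error (SE) from the fit. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and p-values were adjusted over 23 gene lists and 11 lists of cell type markers. The camera test was also run with the correlation estimated for each list. Single values per library, such as the mean log2 CPM of a marker list, were compared with exact two-sided permutation tests, whose smallest p for 4 against 4 libraries is 0.0286.

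The groups, the tests, the lists and the rule for naming genes were chosen before the data were examined. The rule took up to 10 genes with the largest rises and 10 with the largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted genes and pseudogenes. It added up to 4 members with the smallest p of each list described, and Acan, Bcan, Ncan, Vcan, Hapln1, Tnr, Ptprz1, Has2, Has3, Pvalb and Mecp2. The use of the rule on the authors' deposited tables and on the fit with the replicate number as a block was chosen after the data were seen. Has2 was not tested, with 31 counts over all 12 libraries.

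The replicate numbers are shared by the 3 groups, and the labels do not say what a number stands for. Whether they pair the libraries was examined with 28 genes whose level differed by at least 8-fold among the KO ACM libraries at a mean CPM of at least 1, of which 20 were pseudogenes or predicted genes. Over these genes, each NCM and WT ACM library correlated with the KO ACM library of its own number at 0.89 to 0.99 and with libraries of other numbers at no more than 0.08. A single assignment out of 24, or 4.17%, would match the numbers by chance. Over all tested genes, deviations from the group means of same-numbered WT ACM and KO ACM libraries correlated at 0.64, 0.39, 0.34 and 0.57. The same correlations with NCM were 0.37, 0.05, 0.36 and 0.63 for WT ACM and 0.36, 0.07, 0.3 and 0.54 for KO ACM, so that number 2 stayed under 0.1 there. Number 2 of both media correlated more with an NCM library of another number, at 0.17 and 0.15, which goes against the pairing. The numbers were nonetheless taken to pair the libraries, on the evidence of the variable genes, which was chosen after the data were seen. The fit with the replicate number as a block is given beside a result where it changed a call, or a count of calls by over 1.5 times. The labels do not state that the libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries.

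A simulation on the same library sizes and dispersions, with 200 of 15758 genes changed in WT ACM against NCM, recovered 38.8% of genes changed by a log2 of 0.5, 83.6% of those changed by 1 and 98.5% of those changed by 2, with 6 wrong calls among 153. With the measured differences between replicate numbers kept in the simulated libraries, the fit without the block recovered 34.3%, 77.6% and 97%, and the fit with the block 64.2%, 95.5% and 100%. Wrong calls were 0 among 139 without the block and 15 among 188 with it. In a simulated test of lists, 8 of 100 random lists came out with an unadjusted camera p under 0.05, more than the nominal share. The simulated genes varied independently of each other, so this share does not hold for lists whose members vary together.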

Results

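RNA sequencing measured gene expression in primary cultures of cortical neurons from wild-type mouse embryos. The cultures received AraC, which kills dividing cells, on day 3 in vitro to deplete astrocytes. On day 6 they were given medium conditioned by astrocytes with intact Mecp2 (WT ACM), medium conditioned by astrocytes lacking Mecp2 (KO ACM), or medium that had not been on astrocytes (NCM), and RNA was taken on day 12. Each of the 3 groups held 4 libraries, numbered 1 to 4. Mecp2 encodes a methylated-DNA binding protein whose loss causes Rett syndrome, and the title of the series concerns perineuronal nets, the chondroitin sulfate matrix around certain neurons, in neocortex without Mecp2.

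Counts assigned to genes in replicates 1 to 4 came to 20236383, 16570645, 19148488 and 15202763 in NCM. They came to 17798309, 15941524, 19646970 and 22334570 in WT ACM, and to 19791109, 15180531, 18834618 and 19982153 in KO ACM. Exact permutation tests of these totals gave no p under 0.543. ERCC spike-ins took 0.249% to 0.324% of the counts. Mitochondrial transcripts took 5.38 ± 0.558% in NCM, 4.96 ± 0.264% in WT ACM and 5.13 ± 0.235% in KO ACM (SD, n = 4 each), with exact permutation p-values of 0.314 and 0.4 against NCM and 0.429 between the media. On the first principal component NCM replicates 2 and 3, at 27.86 and 27.87, lay far from the conditioned libraries of the same numbers, at -16.51 to 2.99, and near replicate 1 of WT ACM and KO ACM, at 25.54 and 26.31. They held the highest mitochondrial shares, 5.92% and 5.79%.

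**Figure D1:**
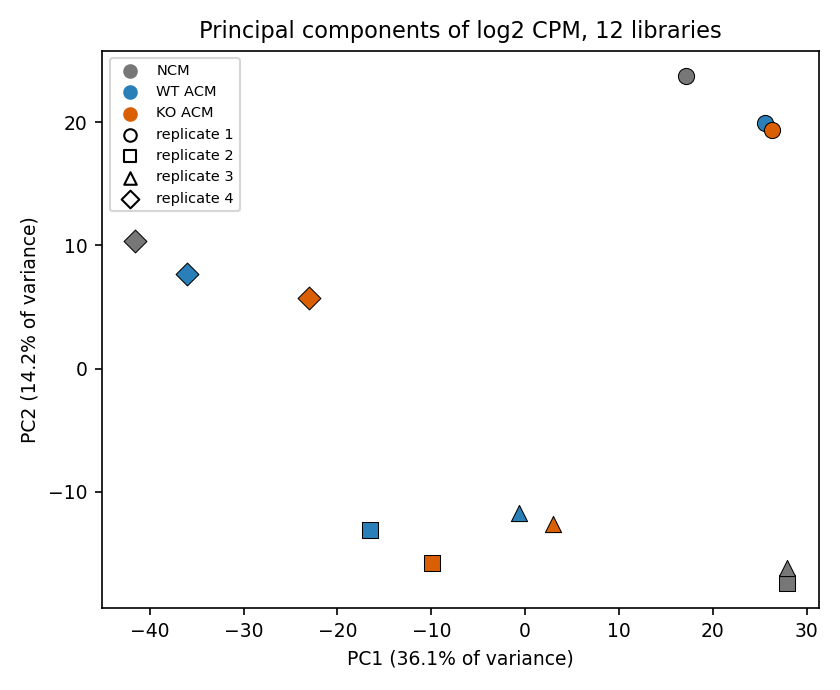
Each point is a library placed by the principal components of log2 CPM, with the component that holds 36.1% of the variance on the horizontal axis and the one that holds 14.2% on the vertical axis, colours for the 3 groups and shapes for the replicate numbers. NCM replicates 2 and 3 lie together at 27.86 and 27.87 on the horizontal axis, far from the same-numbered WT ACM libraries at -16.51 and -0.7 and level with WT ACM replicate 1 at 25.54, from which the vertical axis parts them.

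Neuronal transcripts dominated every culture. The mean log2 CPM of neuron markers was 8.59 ± 0.06 in NCM, 8.6 ± 0.09 in WT ACM and 8.56 ± 0.07 in KO ACM (SD, n = 4 each). Astrocyte markers stood at 3.58 ± 0.24, 3.6 ± 0.19 and 3.61 ± 0.23, and microglia markers at 0.25 ± 0.77, 0.48 ± 0.41 and 0.68 ± 0.22, in the same order. Exact permutation tests on the means of the marker lists gave no adjusted p under 0.786 in any comparison. Their smallest possible p is 0.0286, so a single list adjusted over 11 lists could not pass 0.05, and they left out the replicate numbers. Proliferating cell markers were above the NCM library of the same number in all 4 pairs, by 0.04 to 0.23 in WT ACM and 0.08 to 0.3 in KO ACM. Neuron, astrocyte and microglia markers went both ways over the pairs in each medium. The neurons were wild-type in every group, and Mecp2 (chromosome X, 74026592 to 74135363, GRCm38) was at 169 ± 6.66 CPM in NCM, 170 ± 8.99 in WT ACM and 174 ± 3.55 in KO ACM (SD, n = 4 each), with edgeR adjusted p-values of 0.999, 0.999 and 1. Its level therefore gives no check of which medium a culture received.

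The comparison of WT ACM with NCM asks how neurons responded to factors released by normal astrocytes. Genes of GABAergic interneurons, the inhibitory cells of the cortex, were higher in WT ACM, and genes of endoplasmic reticulum stress, oxidative stress, MAP kinase feedback, neuronal activity and the respiratory chain were lower with all libraries in the fit. These list calls rest on the preset correlation of camera, and none held with an estimated correlation (lowest adjusted p = 0.687). The respiratory chain list passed in the opposite direction without NCM replicates 2 and 3 (adjusted p = 0.0229). The neuropeptide gene Sst (chromosome 16, 23889573 to 23890958) was at 371 ± 85.8 CPM in WT ACM against 233 ± 39.5 in NCM (SD, n = 4 each). With the replicate number as a block it rose by a log2 of 0.66 ± 0.07 (SE, edgeR adjusted p = 0.0191). Klf9 (chromosome 19, 23141226 to 23168134), a transcription factor gene induced by thyroid hormone and glucocorticoids, went from 125 ± 6.88 CPM in NCM to 84.3 ± 9.28 in WT ACM (SD, n = 4 each), a fall by 0.57 ± 0.05 with the block (SE, edgeR adjusted p = 0.00594). Both genes moved the same way in all 4 pairs, and without the block their edgeR adjusted p-values were 0.604 for Sst and 0.537 for Klf9.

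Of 28 GABAergic interneuron genes, 25 were higher in WT ACM, with a median log2 fold change of 0.28 (camera, adjusted p = 3.87e-08; adjusted p = 0.687 with an estimated correlation). The list mean was higher in each of the 4 pairs, by 0.31, 0.43, 0.35 and 0.32. Adjusted over the list alone, 2 members passed upward, against 0 over all genes tested; with the block these counts were 18 and 1. Vip, a neuropeptide gene of another interneuron class, was at 9.31 ± 5.19 against 2.04 ± 2.02 CPM (SD, n = 4 each), a log2 fold change of 2.15 ± 0.57 (SE). Dlx1 (chromosome 2, 71528113 to 71533981), a homeobox gene of interneuron development, was at 86.8 ± 13.4 against 60 ± 16.5 CPM. Its counts may be affected by the overlap with the antisense Dlx1as. The GABA transporter gene Slc6a1 was at 532 ± 67.1 against 428 ± 42.4 CPM. The genes of the GABA-synthesizing enzymes went both ways over pairs 1 to 4. Gad1 differed by a log2 of 0.3, -0.02, -0.01 and 0.11, and Gad2 by 0.16, -0.19, -0.19 and 0.15. Without the block the edgeR adjusted p was 0.713 for Vip, 0.888 for Dlx1 and 0.888 for Slc6a1.

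All 20 genes of endoplasmic reticulum stress and the amino acid response were lower in WT ACM, with a median log2 fold change of -0.45 (camera, adjusted p = 2.24e-08; adjusted p = 0.687 with an estimated correlation). The chaperone gene Hsp90b1 was at 427 ± 66.8 against 568 ± 128 CPM, and Xbp1, a transcription factor of the unfolded protein response, at 74.1 ± 5.66 against 87.2 ± 6.45 (SD, n = 4 each). Of 14 oxidative stress and metallothionein genes, 13 were lower (camera, adjusted p = 0.000606; adjusted p = 0.687 with an estimated correlation), such as the thioredoxin reductase gene Txnrd1 at 93.3 ± 5.88 against 114 ± 11.2 CPM. MAP kinase feedback genes were lower in 12 of 13 cases and activity-regulated genes in 23 of 24 (camera, adjusted p = 0.000764 and 0.00441; adjusted p = 0.708 for each with an estimated correlation). Etv5, an ERK-induced transcription factor gene, was at 31.1 ± 15.9 against 58.2 ± 26.1 CPM, and the neurotrophin gene Bdnf at 61 ± 36.2 against 108 ± 43.3 (SD, n = 4 each). Nuclear-encoded respiratory chain genes were lower in 24 of 25 cases by a median of -0.09 (camera, adjusted p = 0.00441; adjusted p = 0.709 with an estimated correlation), with the succinate dehydrogenase gene Sdha at 230 ± 6.5 against 251 ± 17.7 CPM. Genes of cholesterol synthesis and uptake driven by SREBP2 were higher in 23 of 24 cases by a median of 0.25 (camera, adjusted p = 0.000535; adjusted p = 0.708 with an estimated correlation). The members named here for these groups all had edgeR adjusted p-values over 0.5.

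Several of these groups moved with NCM replicates 2 and 3. The SREBP2 list differed from same-numbered NCM libraries by -0.32, 0.95, 0.9 and -0.16 in numbers 1 to 4, and its direction turned with both libraries left out (camera, adjusted p = 1.71e-05, lower in WT ACM). The respiratory chain list also turned (adjusted p = 0.0229, higher), and the oxidative stress and MAP kinase lists lost their calls (adjusted p = 0.521 and 0.532). The stress list stood at 0.0479, and the GABAergic and activity lists passed at 6.58e-06 and 0.000446. With the block as well, the GABAergic and activity lists passed at 3.97e-09 and 0.0241, and the stress and MAP kinase lists turned to higher without a call (0.636 and 0.181). Markers of microglia and of proliferating cells, which had no call with all libraries, passed upward with both NCM libraries left out (6.58e-06 and 0.0229; 2.23e-05 and 0.047 with the block as well). Leaving out single libraries ended the activity call without NCM replicate 1 and WT ACM replicates 2, 3 and 4 (adjusted p = 0.455, 0.121, 0.0621 and 0.0597). It ended the respiratory call (0.587, 0.211 and 0.176) and the SREBP2 call (0.108, 0.327 and 0.0597) without NCM replicates 2 and 3 and WT ACM replicate 4.

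No camera call was reached by the other lists with all libraries in the fit. Perineuronal net components had 5 of 11 tested members higher, a median log2 fold change of -0.01, a mean of 0.11 and an upward direction in the test (camera, adjusted p = 0.481), so that median and mean differed in sign. With NCM replicates 2 and 3 left out and the block, that list passed upward (adjusted p = 0.0299). Chondroitin sulfate synthesis and sulfation genes had 12 of 17 members lower (adjusted p = 0.105). In that list, 2 members passed downward adjusted over the list alone and 0 over all genes tested, and with the block 0 passed by either count. They were the sulfotransferase genes Chst11, at 57 ± 6.41 against 72.3 ± 7.47 CPM, and Ust, at 38.2 ± 3.12 against 47.2 ± 5.09 (SD, n = 4 each). LXR targets and fatty acid synthesis genes came next below the calls (adjusted p = 0.0757), and mural and meningeal fibroblast markers were lowest in rank (0.965 each).

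The test of single genes in edgeR gave 0 genes with an adjusted p under 0.05 among 15758, with a smallest adjusted p of 0.537 and 818 genes at an unadjusted p under 0.05 (362 higher and 456 lower in WT ACM). DESeq2 called 18 genes (12 up and 6 down), the edgeR exact test 4 (3 up and 1 down) and the fit with the block 2 (1 up and 1 down), the latter with 1821 genes at an unadjusted p under 0.05. Groups without overlap were seen for 184 genes higher and 201 lower, 2.44% of genes against 2.86% for unpaired libraries without an effect. Differences shared by a replicate number make such genes rarer. The 2.86% is thus no fair measure of chance, here or below, if the numbers pair the libraries. In the authors' deposited table for this comparison, 2632 genes had an FDR under 0.05 (1329 up and 1303 down), and a separate list of called genes in the authors' deposited tables held 2379. Of those 2379 genes from the authors' deposited table, 548 (23%) had an unadjusted p under 0.05 in the fit made here. That share, like those given below for the other comparisons, sets unlike fits side by side. With 4 factors estimated from the residuals removed, 2372 of the 2379 genes in the authors' deposited list were called here as well. The fold changes of the authors' deposited table correlated with those computed here at 0.979 across genes, which are not independent replicates. The naming rule was applied to the list of called genes in the authors' deposited tables. There the transcription factor gene Npas3 had a log2 fold change of 1.21 (FDR 9.42e-11), the RNA-editing family gene Adarb2 0.99 (FDR 0.0104) and the interneuron transcription factor gene Npas1 0.85 (FDR 1.42e-05). Genes lower in WT ACM in that list of the authors' deposited tables included Hr, a nuclear receptor corepressor gene, at -0.89 (FDR 3.99e-07), the semaphorin gene Sema7a at -0.60 (FDR 1.29e-15) and Klf9 at -0.57 (FDR 6.93e-07). The authors' deposited table placed 19 members of the GABAergic list up and 2 down, and 19 members of the stress list down.

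The comparison of KO ACM with NCM asks how neurons responded to factors from astrocytes without Mecp2. Interneuron genes were again higher (camera, adjusted p = 4.41e-13; adjusted p = 0.63 with an estimated correlation), and with the replicate number as a block 33 genes passed (20 up and 13 down), each moving the same way in all 4 pairs. That count hung on single libraries. It was 2 without KO ACM replicate 2, 3 or 4, each left out in turn, and 104 without NCM replicate 1. Sst rose from 233 ± 39.5 to 425 ± 39.6 CPM (SD, n = 4 each), by a log2 of 0.89 ± 0.07 (SE, block, edgeR adjusted p = 0.0012). Klf9 fell to 81.2 ± 10.7 CPM, by 0.63 ± 0.05 (SE, block, edgeR adjusted p = 0.0012). Hr (chromosome 14, 70552212 to 70573548) fell from 10.6 ± 2.21 to 5.29 ± 1.11 CPM (SD, n = 4 each), by 1.00 ± 0.13 (SE, block, edgeR adjusted p = 0.0175).

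Among the genes that passed with the block in KO ACM, 5 of the 20 that rose belonged to the GABAergic list, namely Sst, Dlx1, Reln, Erbb4 and Maf. Dlx1, whose counts may be affected by the overlap with Dlx1as, went from 60 ± 16.5 to 94 ± 11.8 CPM (SD, n = 4 each, block, edgeR adjusted p = 0.0126). Reln (chromosome 5, 21884454 to 22344702), which encodes the secreted guidance protein reelin, went from 577 ± 206 to 874 ± 111 CPM (SD, n = 4 each; block, edgeR adjusted p = 0.0175). Erbb4 (chromosome 1, 68032186 to 69108059), a neuregulin receptor gene of interneurons, went from 167 ± 39.7 to 242 ± 38.6 CPM (SD, n = 4 each; block, edgeR adjusted p = 0.0247). The epidermal growth factor receptor gene Egfr rose from 10.3 ± 2.57 to 17.8 ± 2.42 CPM (block, edgeR adjusted p = 0.00737), Adarb2 from 66.8 ± 30.3 to 141 ± 11.5 CPM (0.0462) and Npas3 from 6.29 ± 2.43 to 14 ± 0.221 CPM (0.0462; SD, n = 4 each). Falls included the potassium channel gene Kcna1, by 0.40 (block, edgeR adjusted p = 0.0222), and the sorting receptor gene Sorl1, by 0.35 (block, edgeR adjusted p = 0.0126). Without the block the edgeR adjusted p was 0.291 for Sst and Klf9, 0.315 for Hr and 0.636 for Dlx1.

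In KO ACM, 26 of the 28 GABAergic interneuron genes were higher than in NCM, by a median log2 of 0.38 (camera, adjusted p = 4.41e-13; adjusted p = 0.63 with an estimated correlation). The list mean was higher by 0.24, 0.54, 0.46 and 0.52 in the 4 pairs. Gad1 was higher by a log2 of 0.26, 0.18, 0.16 and 0.41 in pairs 1 to 4, while Gad2 differed by 0.06, -0.03, -0.04 and 0.41. Adjusted over the list alone, 10 members passed upward and 0 over all genes tested; with the block 22 and 5 did. Slc6a1 was at 578 ± 56.8 CPM, the potassium channel gene Kcnc2 at 85.2 ± 9.73 against 64.3 ± 6.22, and Vip at 10.2 ± 4.78 (SD, n = 4 each), with edgeR adjusted p-values of 0.537, 0.545 and 0.609. Microglia and macrophage markers were higher in 10 of 13 cases by a median of 0.37 (camera, adjusted p = 0.0308; adjusted p = 0.688 with an estimated correlation). Their levels were low, such as Mrc1 at 0.97 ± 0.292 against 0.534 ± 0.272 CPM (SD, n = 4 each), and the call was lost with a filter of 1 CPM in 4 libraries (adjusted p = 0.327). It held in 7 of 12 fits that left out a library, and was lost without NCM replicates 1 and 4 (0.834 and 0.174) and KO ACM replicates 1, 3 and 4 (0.198, 0.0629 and 0.0697), each left out in turn. Markers of proliferating cells were higher in 11 of 17 cases (camera, adjusted p = 0.0546), which the block brought to 0.0259 (adjusted p = 0.433 with block and estimated correlation). The CPM filter brought it to 0.0396, and leaving out NCM replicates 2 and 3 to 0.0328 (0.0707 with the block as well). Tpx2, a spindle protein gene, was at 5.57 ± 0.415 against 4.36 ± 0.499 CPM (SD, n = 4 each).

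All 20 stress genes were lower in KO ACM, by a median log2 of -0.39 (camera, adjusted p = 9.33e-07; adjusted p = 0.688 with an estimated correlation). Oxidative stress genes were lower in 12 of 14 cases, and MAP kinase feedback genes in all 13 (camera, adjusted p = 0.00191 and 0.0139; adjusted p = 0.688 for each with an estimated correlation). Activity-regulated genes were lower in 23 of 24 cases and respiratory chain genes in 23 of 25, and SREBP2 targets were higher in 21 of 24 (camera, adjusted p = 0.0328, 0.0308 and 0.0308; adjusted p = 0.688 for each with an estimated correlation). In the oxidative stress list, Txnrd1 was at 90.6 ± 8.64 CPM and the glutathione reductase gene Gsr at 26 ± 0.474 against 31.4 ± 4.01 (SD, n = 4 each); 2 members passed downward adjusted over the list alone (3 with the block) and 0 over all genes tested. With NCM replicates 2 and 3 left out, the stress and oxidative stress calls were lost (adjusted p = 0.214 and 0.679), and the MAP kinase list changed direction (0.963). With the block as well, the MAP kinase list passed upward (0.00948) and the stress list turned to higher without a call (0.114). The respiratory chain and SREBP2 lists passed in the opposite direction without the block (0.00797 higher and 1.53e-08 lower) and with it (0.00211 and 4.47e-15). The GABAergic, microglia and activity lists passed without the block (1.53e-08, 1.25e-07 and 0.00797), but with the block as well the activity list did not (adjusted p = 0.722), its differences from NCM being -0.25 in pair 1 and 0.16 in pair 4. Leaving out single libraries ended the activity call without NCM replicate 1 and KO ACM replicates 2, 3 and 4 (adjusted p = 0.835, 0.281, 0.219 and 0.166). It ended the MAP kinase call without NCM replicates 1, 2 and 3 (0.0755, 0.162 and 0.132) and KO ACM replicates 2 and 4 (0.109 and 0.128). The respiratory call was lost without NCM replicates 2 and 3 (0.787 and 0.392) and KO ACM replicates 2 and 4 (0.109 and 0.406), and the SREBP2 call without the same libraries (0.787, 0.786, 0.109 and 0.321), with its direction turned without NCM replicate 3.

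Perineuronal net components had 6 of 11 members higher in KO ACM than in NCM by a median of 0.15 (camera, adjusted p = 0.213). With NCM replicates 2 and 3 left out and the block, that list passed upward (adjusted p = 0.0191). Chondroitin sulfate synthesis genes had 9 of 17 members lower (adjusted p = 0.291). The remaining lists had adjusted p-values up to 0.905, that of the erythroid markers. Without the block edgeR called 0 genes in KO ACM against NCM, with a smallest adjusted p of 0.291 and 847 genes at an unadjusted p under 0.05 (425 up and 422 down). DESeq2 called 25 (17 up and 8 down) and the edgeR exact test 17 (14 up and 3 down). Groups without overlap were seen for 176 genes higher and 209 lower, 2.44% against 2.86% for unpaired libraries without an effect. The authors' deposited table for this comparison held 1930 entries with an FDR under 0.05 (1015 up and 915 down), of which 5 were spike-ins. Of the genes called in the authors' deposited table, 544 (28.4%) had an unadjusted p under 0.05 in the fit made here, and 30 of the 33 genes called with the block were among those of the authors' deposited table. The largest rises that the naming rule takes from the authors' deposited table included the collagen gene Col14a1 at 1.53 (FDR 3.92e-11), the retinol carrier gene Rbp4 at 1.25 and Npas3 at 1.20 (FDR 1.43e-10). The authors' deposited table also had the homeobox gene Prox1 at 1.04 (FDR 6.79e-09), the somatostatin-related Cort at 0.89 (FDR 2.71e-05) and, with the largest rise of these, Vip (FDR 0.0444). The authors' deposited table placed 23 members of the GABAergic list up and 2 down.

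The comparison of KO ACM with WT ACM asks whether loss of Mecp2 in the astrocytes alters what their medium does to neurons. No gene or list passed the test without the block, and the levels of the interneuron genes in the media lay close together. Sst was at 425 ± 39.6 CPM in KO ACM against 371 ± 85.8 in WT ACM (SD, n = 4 each), a log2 fold change of 0.20 ± 0.16 (SE), and Cort at 15.7 ± 4.07 against 12.5 ± 6.63 (edgeR adjusted p = 1 for both). Of the 28 GABAergic interneuron genes, 24 were higher in KO ACM, by a median of 0.10 (camera, adjusted p = 0.104). The block brought this list to an adjusted p of 0.000447 (adjusted p = 0.926 with block and estimated correlation), with list means that differed by -0.07, 0.11, 0.11 and 0.2 in the 4 pairs. The call of the list alone without the block was reached in 3 of 12 fits that left out a library, with adjusted p-values from 0.00124 to 0.948.

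SREBP2 targets were lower in KO ACM than in WT ACM in 23 of 24 cases, and microglia markers higher in 11 of 13 (camera, adjusted p = 0.229 for each). Mrc1, a macrophage receptor gene, had a log2 fold change of 0.82 ± 0.36 and the contractile gene Acta2, a mural cell marker, 0.85 ± 0.55 (SE). Inflammatory and acute-phase genes had the highest adjusted p, 0.999. With NCM replicates 2 and 3 left out and the block, 6 lists passed, 4 higher and 2 lower in KO ACM. The lower ones were SREBP2 targets (camera, adjusted p = 6.43e-09) and glutamatergic projection neuron genes (0.00758). In KO ACM against WT ACM edgeR gave 0 genes with an adjusted p under 0.05 and 150 at an unadjusted p under 0.05 (72 up and 78 down), 0.952% of genes. DESeq2, the edgeR exact test and the fit with the block also called 0, the latter with 349 genes at an unadjusted p under 0.05. Groups without overlap were seen for 61 genes higher and 92 lower, 0.971% against 2.86% for unpaired libraries without an effect. The authors' deposited table held 94 genes with an FDR under 0.05 (49 up and 45 down), of which 3 (3.19%) had an unadjusted p under 0.05 in the fit made here. From the authors' deposited table the naming rule takes Ttc9b (chromosome 7, 27653915 to 27657346) alone, with a log2 fold change of -0.25 (FDR 0.0186). Its level here was 28.7 ± 1.32 CPM in KO ACM against 34.2 ± 2.86 in WT ACM (SD, n = 4 each; edgeR adjusted p = 1). Recovery of known changes was simulated for WT ACM against NCM and not for this comparison. There, with the differences between numbers kept, 34.3% of genes changed by a log2 of 0.5 were recovered without the block and 64.2% with it.

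Genes of the perineuronal net are the subject named in the title of the series. Hapln1 (chromosome 13, 89539796 to 89611652), which encodes a link protein that ties proteoglycans to hyaluronan, was at 69.7 ± 47.4 CPM in NCM, 114 ± 29.9 in WT ACM and 129 ± 20.4 in KO ACM (SD, n = 4 each). It was higher in every conditioned library than in the NCM library of its number. The log2 fold changes against NCM, 0.71 ± 0.39 and 0.89 ± 0.39 (SE), did not pass in edgeR (adjusted p = 0.934 and 0.915; 0.335 and 0.179 with the block). The NCM libraries themselves spread from 26.9 and 35.3 CPM in replicates 2 and 3 to 89 and 128 CPM in replicates 4 and 1. KO ACM exceeded WT ACM in all 4 pairs, at 160, 119, 118 and 119 CPM against 158, 105, 91.1 and 102. The log2 fold change was 0.18 ± 0.39 (SE, edgeR adjusted p = 1). That SE is from the fit without the block, so it takes in the differences between numbers and does not measure the spread of the pairs. Acan (chromosome 7, 79053483 to 79115099), the gene of the net proteoglycan aggrecan, was at 51 ± 21.2 CPM in NCM, 40.6 ± 23.4 in WT ACM and 43.1 ± 21.7 in KO ACM (SD, n = 4 each), with edgeR adjusted p-values of 0.96, 0.999 and 1. Vcan (chromosome 13, 89655312 to 89742509), the versican gene, was at 59 ± 33.1, 90.9 ± 18.7 and 95.5 ± 23.8 CPM, and Tnr, the tenascin-R gene, at 180 ± 49.7, 216 ± 36 and 201 ± 20.3 CPM (SD, n = 4 each).

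The neurocan gene Ncan was at 298 ± 11.3 CPM in NCM, 276 ± 14.8 in WT ACM and 282 ± 14.4 in KO ACM, and the brevican gene Bcan at 4 ± 0.395, 3.98 ± 0.337 and 5.09 ± 1.39 CPM (SD, n = 4 each). The receptor phosphatase gene Ptprz1 stood at 139 ± 26.2, 145 ± 24 and 155 ± 20.2 CPM, the hyaluronan synthase gene Has3 at 20.5 ± 1.74, 19.8 ± 1.87 and 19.1 ± 3.77, and the interneuron gene Pvalb at 0.781 ± 0.532, 1.77 ± 0.625 and 1.61 ± 1.03 (SD, n = 4 each). None of these genes had an edgeR adjusted p under 0.05 with all libraries in the fit, with or without the block. With NCM replicates 2 and 3 left out and the block, which leaves 2 NCM libraries, 3 net genes were called higher in both media. Hapln1 then had log2 fold changes of 0.22 in WT ACM and 0.41 in KO ACM (edgeR adjusted p = 0.0454 and 4.24e-05), and Ptprz1 0.25 and 0.35 (0.0043 and 2.73e-05). Acan turned from lower to higher, at 0.38 and 0.50 (edgeR adjusted p = 0.0448 and 0.00216), and Vcan was called in KO ACM alone (0.19, adjusted p = 0.0313, and 0.343 in WT ACM). In pairs 2 and 3, left out after the data were seen, Acan differed by -1.44 and -0.65 in WT ACM and -1.15 and -0.9 in KO ACM. Its upward call thus followed from the choice of libraries. Ptprz1 there was at 128 and 146 CPM in WT ACM and 140 and 161 in KO ACM, against 149 and 156 in NCM. With 2 NCM libraries, these p-values hold little of the spread between NCM libraries. In the authors' deposited tables Hapln1 had log2 fold changes of 0.96 (FDR 3.9e-28) for WT ACM against NCM, 1.16 (FDR 1.84e-11) for KO ACM against NCM and 0.20 (FDR 0.0471) for KO ACM against WT ACM. The WT ACM against NCM values stood in the table of all genes. Its fold changes came closest to a fit made here with 5 factors estimated from the residuals removed (r = 0.99978). The KO ACM against NCM fold changes came closest with 4 factors removed (r = 0.99999), so their FDR values may come from unlike fits. The authors' deposited tables gave Vcan 0.75 (FDR 2.79e-05) and 0.83 (FDR 1.37e-07), Tnr 0.29 (FDR 2.49e-13) and 0.20 (FDR 1.23e-06), and Acan -0.34 (FDR 0.00454) and -0.24 (FDR 0.078) against NCM. In the same order, the authors' deposited tables gave Ncan -0.11 (FDR 0.000607) and -0.08 (FDR 0.0463), and Ptprz1 0.06 (FDR 0.126) and 0.16 (FDR 0.000187).

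**Figure D2:**
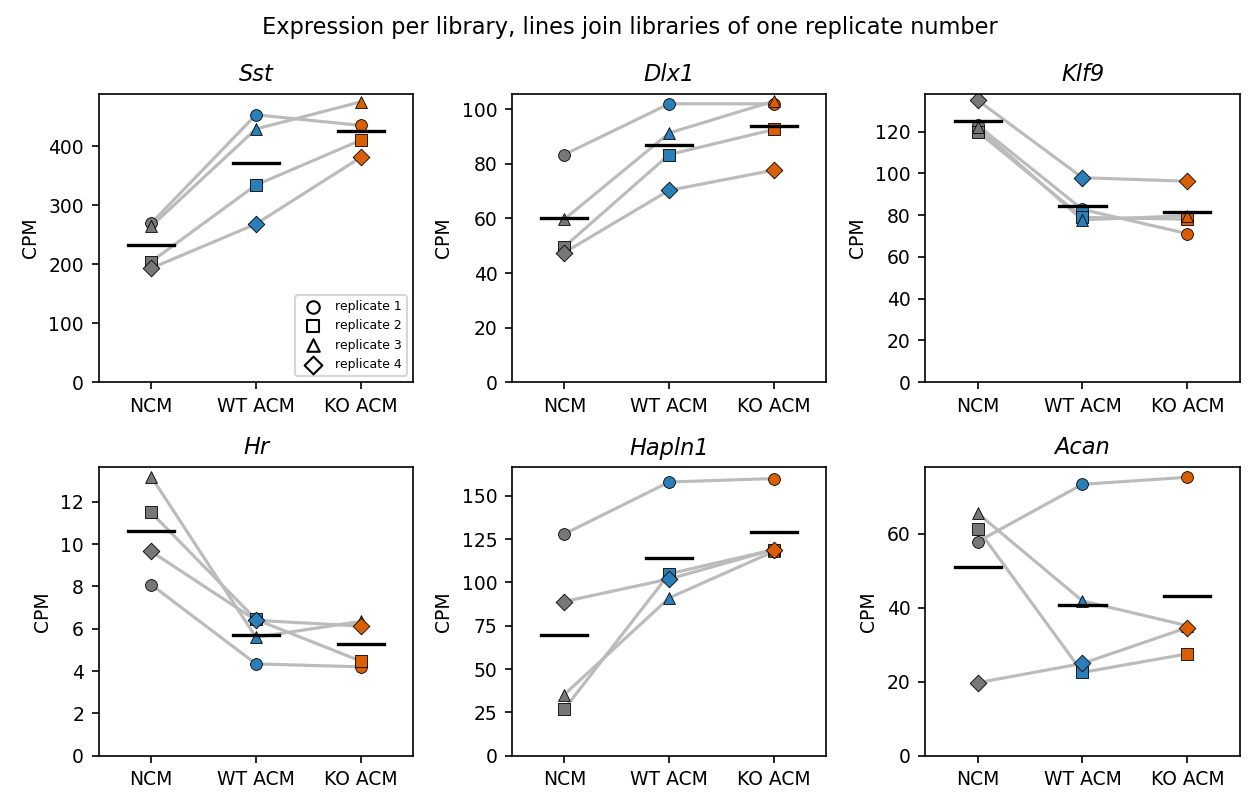
Points give the CPM of each library for Sst, Dlx1, Klf9, Hr, Hapln1 and Acan in NCM, WT ACM and KO ACM, bars give group means, and grey lines join libraries with the same replicate number. Klf9 falls and Sst rises along every line from NCM, whereas Hapln1 in NCM lies at 26.9 and 35.3 in replicates 2 and 3 and at 128 and 89 in replicates 1 and 4.

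**Figure D3:**
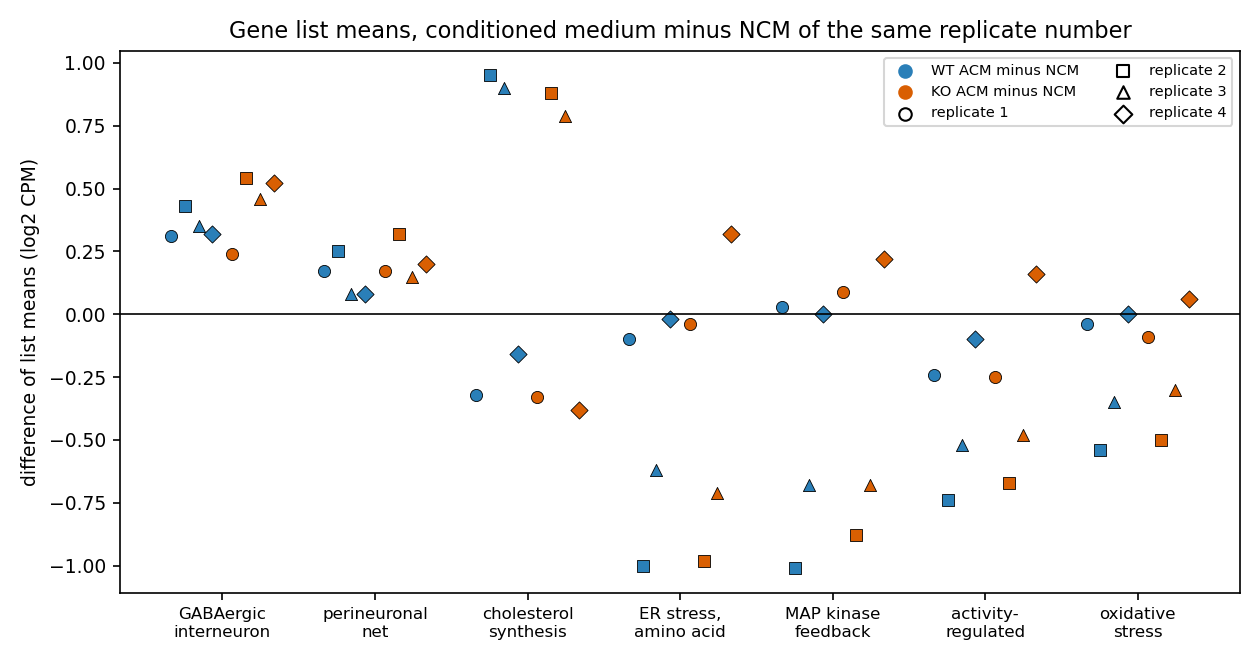
Each point is the difference in mean log2 CPM of a gene list between a conditioned library and the NCM library with the same replicate number, for 7 lists on the horizontal axis, with colours for WT ACM and KO ACM. The GABAergic list lies above 0 in all 4 pairs, between 0.24 and 0.54, while the SREBP2 list is between 0.79 and 0.95 in pairs 2 and 3 and between -0.38 and -0.16 in pairs 1 and 4.

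How far the responses to the media ran in parallel was examined across genes. Log2 fold changes against NCM correlated at 0.74 between WT ACM and KO ACM over 15758 genes, which are not independent replicates, with a covariance of 0.0443. Because the comparisons share the NCM libraries, simulated groups with no effect gave a correlation of 0.5 (0.48 to 0.53 over 20 simulations) and a covariance of 0.0332, or 0.0204 with the differences between numbers kept. With the NCM libraries shared out so that each comparison had 2 of its own, the correlation was 0.05 (-0.16 to 0.19 over 6 ways) and the covariance 0.00406. The shares held NCM libraries of different replicate numbers, while all conditioned libraries stayed in. Differences between numbers thus entered the comparisons with opposite sign and lowered both values. No simulation was made for that design, so the drop does not show how much of the response was shared.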

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

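The splits of the gene counts with and without the block and of the list counts were planned; the tests of residual factors, of NCM replicates 2 and 3, of the embryo pools and of the GABAergic list were chosen only after the results were seen.

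A library stood far from the other 3 of its group in 9 of 165 groups examined, 5.45%, and chance gives about 1 in 20. Acan was at 19.7 CPM in NCM replicate 4 against 57.8 to 65.5 in the others, and at 75.2 CPM in KO ACM replicate 1 against 27.5 to 35.1. Hapln1 was at 160 CPM in KO ACM replicate 1 against 118 to 119 in the others. Ptprz1 was at 100 CPM in NCM replicate 4 against 149 to 156. The mean log2 CPM of voltage-gated channel genes was 6.96 in KO ACM replicate 1 against 7.06 to 7.07, that of activity-regulated genes 5.03 in WT ACM replicate 1 against 3.49 to 3.67, and that of MAP kinase feedback genes 4.65 in KO ACM replicate 1 against 3.87 to 3.99. Insulin and IGF system genes were at 4.93 in KO ACM replicate 2 against 4.96 in each of the others, and neuron markers at 8.69 in NCM replicate 4 against 8.55 to 8.57. In the authors' deposited table of KO ACM against NCM, 5 of 21 spike-ins had an FDR under 0.05. Spike-ins are not made by cells, but their level relative to the RNA of the cells can differ between groups. They took 0.268 ± 0.0156% of the counts in KO ACM and 0.297 ± 0.0242% in NCM (SD, exact permutation p = 0.143). The authors' deposited list of called genes for that comparison held 1 spike-in. In the authors' deposited tables of each other comparison 0 of 21 spike-ins had an FDR under 0.05.

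The authors' deposited tables hold 2632 and 1930 entries under the threshold against NCM where the edgeR fit made here called 0 genes (818 and 847 at an unadjusted p under 0.05; DESeq2 18 and 25). The authors' choice of genes is argued against as the cause, since an edgeR fit on the same entries with no factor removed called 0 genes in KO ACM against NCM. Removal of factors estimated from the residuals may account for the calls: with 4 factors removed, 1916 entries were called in KO ACM against NCM, of which 1903 stood in the authors' deposited list of called genes. In WT ACM against NCM, removal of 4 factors shared 2372 of the 2379 genes in the authors' deposited list of called genes. Removal of 5 factors shared 2630 of the 2632 entries in the authors' deposited table of all genes. With 4 factors, 13 of 35 splits of the libraries gave as many genes as the 2485 of WT ACM against NCM (highest other 6138), 17 of 35 as many as the 1968 of KO ACM against NCM (5386) and 27 of 35 as many as the 106 of KO ACM against WT ACM (4610), so chance cannot be excluded for these counts. Among the 8 splits that part every pair, the others gave 4 to 2740, 4 to 3099 and 0 to 110.

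NCM replicates 2 and 3 held the rise of the SREBP2 list, the fall of the stress list and most of the Hapln1 difference. The genotype of embryo pools 2 and 3 is argued against, since the SREBP2 list differed by only -0.07 between conditioned libraries 2 and 3 and libraries 1 and 4, beside -1.25 in NCM. Lower depth is also argued against, as the smaller total of both libraries was 16.57 M counts and KO ACM replicate 2, at 15.18 M, had a SREBP2 list mean of 6.59 beside 5.71 and 5.51 in those libraries. RNA or culture quality may have differed, with mitochondrial shares at least 0.4 percentage points above every other library, but no direct measure of quality decides it and it cannot be told apart from a difference in the NCM itself. An effect of conditioned medium present in cultures 2 and 3 alone also stays open, as untested.

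Some genes followed the replicate number in all 3 groups, such as Cwc22 at 253, 471, 363 and 26.1 CPM in NCM and 246, 523, 376 and 27.1 CPM in KO ACM. The numbers held a median of 0.24 of the within-group variance of 39 spike-ins, where chance gives 0.33. They held 0.56 of that of all tested genes and 0.99 of that of the 28 variable genes. Spike-ins thus gave no sign of library preparation by number. Spike-ins with a mean count as low as 10 were included, so counting noise may hide such a difference. Preparation by number is therefore not excluded. Pools of embryos that differ in genotype are a candidate explanation, with a lowest same-number correlation of 0.89. The labels name no pools, and the variable genes were picked from the KO ACM libraries alone.

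Other splits of the 8 libraries of each comparison were tested with the same fits. Without the block each real comparison gave 0 genes, which all 35 splits reach by construction, and the highest other counts were 2399 for WT ACM against NCM, 532 for KO ACM against NCM and 1 for KO ACM against WT ACM. The split with 2399 genes joined NCM replicates 1, 2 and 3 with WT ACM replicate 1, and so points to a structure of the samples other than the media. With the block, 2 of 35 splits gave as many as the 2 genes of WT ACM against NCM (highest other 462), so chance cannot be excluded, while 1 of 35, the real one, gave 33 genes in KO ACM against NCM (highest other 8). For KO ACM against WT ACM with the block the real count was 0, again reached by construction, and the highest of the other splits, 3229, set replicates 1 and 4 against 2 and 3, the structure of the replicate numbers. Among the 8 splits that part every pair, the fair comparison if the numbers pair the libraries, all others gave 0 genes with the block in each comparison, but 8 splits are too few for a share under 0.05. Lists passing numbered 7 and 8 against NCM, and 19 and 14 of 35 splits gave as many (highest other 14 in each), so chance cannot be excluded for these counts. Between the media 0 lists passed, which says nothing of chance since any split gives at least as many (highest other 10).

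The GABAergic list was also tested over the splits by itself. Its camera p without the block was 2.28e-09 in WT ACM against NCM, as small in 3 of 35 splits (lowest other 8.72e-17), and 1.3e-14 in KO ACM against NCM, as small in 1 of 35 (lowest other 4.46e-13). With the block the real split alone, 1 of 35, reached 9.88e-14 and 1.81e-20 against NCM (lowest others 3.7e-12 and 6.34e-13). Among the 8 splits that part every pair the real one was also alone (lowest others 5.26e-06 and 7.34e-07), but 8 are too few for a share under 0.05, and the list was picked after its result was seen. Between the media it was 0.00306 without the block, as small in 14 of 35 splits (lowest other 3.02e-07), and 1.32e-05 with it, as small in 4 of 35 (2.87e-08), so chance cannot be excluded for that difference.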

How the results depend on the processing

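The residual-factor fits, the fits without NCM replicates 2 and 3, and the camera test with block and estimated correlation were chosen only after the data were seen; the other alternatives were planned. The naming rule applied without the block gave 175 gene results with no call, which leave out Klf9, Hr and other genes named from the fit with the block; 2 of them (Sst against NCM in each medium) passed under an alternative that was planned. Over all alternatives, these gene results kept direction and side in 4466 cases, gained a call in 304 and changed direction in 101, of which 22 and 34 came with NCM replicates 2 and 3 left out, without and with the block. Acan against NCM was among them, and passed upward in the latter fit (0.38 in WT ACM and 0.50 in KO ACM). Of 39 results for 13 lists, direction and side were kept in 598 fits, a call was lost in 69 and gained in 30, and direction turned in 14 for lists that had passed and in 30 for lists that had not. Scaling moved the median log2 fold change of all genes by at most 0.0201. The cause was not tested for any change below.

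The counts of genes for WT ACM against NCM, KO ACM against NCM and KO ACM against WT ACM, 0 in edgeR for each, were 18, 25 and 0 in DESeq2 and 4, 17 and 0 in the edgeR exact test. With 1 to 5 residual factors removed they were 358, 1086, 1995, 2485 and 2750 for WT ACM against NCM, 140, 567, 1508, 1968 and 2231 for KO ACM against NCM, and 0, 0, 15, 106 and 214 for KO ACM against WT ACM. RLE and upper-quartile factors, plain library sizes, no filter, a CPM filter and fits of 8 libraries gave 0. Leaving out a library gave 0 to 2, 0 to 3 and 0, with the highest counts without NCM replicate 1.

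With the replicate number as a block, the pairing gave 2, 33 and 0 genes and 7, 9 and 1 lists, the added lists being proliferating cell markers in KO ACM against NCM (adjusted p = 0.0259) and the GABAergic list in KO ACM against WT ACM (0.000447). The block changed no other call over all genes tested and no other list call. It did change counts adjusted over the list alone: in WT ACM against NCM, chondroitin sulfate genes went from 2 lower to 0, GABA receptor genes from 0 to 1 higher and 3 lower, and activity-regulated and stress genes from 0 to 9 lower each, and in KO ACM against NCM oxidative stress genes from 2 lower to 3 and perineuronal net components from 0 to 1 higher. GABAergic genes went from 2 higher to 18 higher and 1 lower in WT ACM and from 10 to 22 higher in KO ACM, and other lists changed by 1 to 3 genes in a direction. Leaving out a library or a number gave 0 to 78 genes for WT ACM against NCM (78 without NCM replicate 1), 0 to 104 for KO ACM against NCM (104 without NCM replicate 1, 0 without number 3) and 0 for KO ACM against WT ACM.

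The counts of lists, 7, 8 and 0, were 0, 0 and 0 with an estimated correlation, with or without the block. Without a library they ranged over 4 to 10, 3 to 10 and 0 to 4. With NCM replicates 2 and 3 left out, 0 genes passed in edgeR in each comparison (530 and 762 at an unadjusted p under 0.05 against NCM) and 9, 8 and 1 lists; with the block as well, 303, 879 and 0 genes and 17, 15 and 6 lists passed.

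Directions of lists turned when NCM replicates 2 and 3 were left out. In WT ACM against NCM, the respiratory chain (adjusted p = 0.0229) and SREBP2 (1.71e-05) lists turned, as did MAP kinase (0.963), respiratory chain (0.00797) and SREBP2 (1.53e-08) in KO ACM against NCM. With the block as well, stress (0.636), MAP kinase (0.181), respiratory chain (0.00427) and SREBP2 (1.15e-10) turned in WT ACM against NCM, and stress (0.114), MAP kinase (0.00948), respiratory chain (0.00211) and SREBP2 (4.47e-15) in KO ACM against NCM. Lists that had not passed also turned: glutamatergic projection neuron genes went from higher to lower with NCM replicates 2 and 3 left out (0.266 in WT ACM and 0.0976 in KO ACM) and passed with the block as well (0.0347 and 0.00211), and TGF-beta and BMP target genes went from lower to higher without a call (0.311 and 0.851; 0.425 and 0.811 with the block). Perineuronal net components kept their direction and passed with both changes (0.0299 and 0.0191). SREBP2 in KO ACM against NCM also turned without NCM replicate 3 alone (0.786), and its adjusted p without a library ranged from 2.27e-07 to 0.787.

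The adjusted p of the GABAergic list without a library ranged from 2.98e-14 to 0.002 in WT ACM against NCM and from 7.54e-15 to 3.38e-06 in KO ACM against NCM. The correlation of the responses, 0.74, was 0.05 with 2 NCM libraries for each comparison, 0.79 with the CPM filter, 0.73 with the block, 0.81 without NCM replicates 2 and 3, and 0.62 (without KO ACM replicate 4) to 0.84 (without NCM replicate 4) without a library. The drop to 0.05 cannot be put down to the shared NCM libraries alone, since the NCM libraries of each comparison then had different replicate numbers. Depth limited the genes with few counts, such as Has2 with 31.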

Other observations

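The comparison of both conditioned media with NCM, and the tests of interneuron share and of hormone-induced genes, were chosen only after the results were seen.

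Taking both conditioned media against NCM with the replicate number as a block, 54 genes passed in edgeR (29 up and 25 down), of which 7 that rose belong to the GABAergic list, and each moved the same way in all 4 replicate numbers. Without the block 0 passed, with 1123 at an unadjusted p under 0.05, against 2219 with it. Klf9 fell by 0.60 ± 0.04 (SE, adjusted p = 0.000701) and Hr by 0.95 ± 0.11 (0.00867). Sst rose by 0.77 ± 0.07 (adjusted p = 0.00133), Dlx1 by 0.61 (0.00867), Reln by 0.55 (0.0184), Erbb4 by 0.46 (0.027), the transcription factor genes Maf by 0.25 (0.032) and Mafb by 0.42 (0.0356), and the GABA transporter gene Slc6a1 by 0.37 (0.0447). The growth factor gene Fgf10 rose by 1.26 ± 0.22 (adjusted p = 0.0447) and Egfr by 0.68 (0.00792). Falls included the myelin protein gene Mbp by 0.40 ± 0.07 (adjusted p = 0.0396), the glutamate transporter gene Slc1a2 by 0.25 (0.032), the pentraxin gene Nptx1 by 0.41 (0.0447), the cell adhesion gene Opcml by 0.27 (0.00792) and the potassium channel gene Kcna1 by 0.40.

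A hypothesis for the higher interneuron genes is that conditioned medium left a larger share of all GABAergic neurons with no change within them. Genes of all GABAergic neurons would then rise alike, provided that no other cells expressed them, which was not tested. In 9 such genes the rises differed by more than their errors, with a Q of 46.5 on 8 degrees of freedom. The chi-squared p for equal rises was 1.91e-07, taking the genes' errors as independent. Gad2, the GABA-synthesizing enzyme gene, was at 0.04 ± 0.07, Gad1 at 0.17 ± 0.05, the vesicular transporter gene Slc32a1 at 0.15 ± 0.08 and Dlx1 at 0.61 ± 0.07 (log2, SE). Under that assumption a uniform gain is argued against with all libraries in the fit, but the test was not repeated without NCM replicates 2 and 3. In pairs 2 and 3 Gad2 differed by -0.11 each, Slc6a1 by 0.59 and 0.47 and Dlx1 by 0.83 and 0.7. The rises lay closer together in pairs 1 and 4, with Gad2 at 0.11 and 0.28, Slc6a1 at 0.22 and 0.2 and Dlx1 at 0.29 and 0.64. A uniform gain stays open for those pairs. Survival of certain interneuron classes, or a change of expression within interneurons, may be at work, and bulk RNA does not separate these.

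Klf9 and Hr are both induced by thyroid hormone, and Klf9 also by glucocorticoids, so the loss of hormone from the medium by contact with astrocytes could lower both. Of 12 other thyroid hormone-induced genes tested, 8 were lower in WT ACM than in NCM, with a median of -0.08. In KO ACM 6 of them were higher and 6 lower than in NCM, with a median of -0.01. The camera p of these genes was 0.227 in WT ACM and 0.41 in KO ACM. Glucocorticoid-induced genes gave a camera p of 0.466 in WT ACM and 0.777 in KO ACM. Neither hypothesis was supported or excluded, since a list with members that go both ways leaves it open.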
